A study of Homo sapiens with 21 samples.

How the data were processed

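The series held mRNA sequencing of 3p loss, 3q gain and chromosome 3 WT cells, RPF sequencing of 3p loss cells and of WT cells labelled 3p WT, and mRNA sequencing of 8p loss and 8p WT cells, with 3 libraries in each of 7 groups. Per the labels, the chromosome 3 mRNA libraries were read at 100 bp, and cells for RPF were treated with cycloheximide for 5 min before footprints were isolated with the RiboLace Pro kit. Per the labels, reads were aligned to GRCh38. The aligner, the counting program and the gene annotation were not given in the sources used here.

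The RPF table as deposited held whole-number counts of footprints per gene, with no normalization by the authors, in 20915 gene names. Of these, 1061 were named by transcript and left out of library sizes and tests, since they name no gene. They held 0.432 to 0.568% of the counts. The mRNA tables as deposited held values that the authors had scaled for length and library size, taken here as TPM from their column sums. No unit was named, and FPKM, a similar scale, was not excluded. These tables held protein-coding genes, 17756 in the chromosome 3 set and 20066 in the chromosome 8 set, where 30 entries sharing a name with another were summed to give 20036 names. Positions came from the RefSeq table of GRCh38 and were matched by symbol, then by a synonym, then by Ensembl identifier. A position was found for 94.8% of RPF names, 96.9% of chromosome 8 names and 17748 of 17756 chromosome 3 names. Chromosome 3 was split into arms at 91 Mb and chromosome 8 at 45 Mb. The columns of per-sample values not used numbered 0.

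Changes in mRNA were tested in limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(TPM + 1), for genes with a mean of at least 1 TPM. The 9 chromosome 3 libraries were fitted together and the 6 chromosome 8 libraries on their own. RPF counts were tested in edgeR 4.0.16 with its quasi-likelihood F test, TMM factors and filterByExpr, and log2 CPM used a prior count of 2. Translational efficiency was tested in limma as the interaction of assay and genotype on log2(TPM + 1) and log2(CPM + 1). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The arm level of a library was the mean of the arm's tested genes minus the mean of tested genes on other autosomes. Groups were compared on it by an exact two-sided permutation of libraries, and the arm was tested as a set in camera with a preset correlation of 0.01 and with an estimated one. Shares of the copy-number change had bootstrap intervals from 2000 draws of genes, which do not hold the spread between libraries. Complex subunit genes were compared with other genes of the arm by a two-sided permutation test with 100000 resamples. Windows were 10 Mb with at least 5 genes. Gene lists with at least 5 tested members were run in camera on genes off the altered arms. Correlations of fold changes across comparisons left out chromosomes 3 and 8, and the effect of shared WT libraries was simulated in 200 sets with no effect, and in 50 such sets for shared calls, a count added after the results were seen.

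Genes named in the text followed a rule. Per comparison it took the 8 largest positive and 8 largest negative changes among called genes whose libraries do not overlap between groups. These needed a mean of at least 10 CPM or 5 TPM in the higher group. It added the 4 largest changes with and the 4 largest against the copy number on the altered arm, the tested members of a fixed list of known genes of the arm, and 2 to 4 called members with the highest level of each list described. From these, the text gives mainly genes whose calls held in every alternative. XIST and Y-linked genes were left out. The tests, comparisons, lists, rule and main alternatives were fixed before the data were examined.

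RPF totals of 4622326 to 13607875 counts set the precision of footprint values, and the depth behind TPM is unknown. The tests were tried on simulated data, with 100 genes raised or lowered by 1.5-fold and 100 by 2-fold in libraries of each set. Of the 2-fold changes, the tests recovered 40 in 3p loss mRNA, 57 in 3q gain, 50 in their direct contrast, 90 in RPF, 32 in translational efficiency and 91 in 8p loss. False calls were 2.74 to 7.14% of the calls in those sets. The simulated noise was independent between genes and libraries. It therefore does not cover shifts of whole arms in single libraries or the closeness of RPF replicates 1 and 2. Alternatives were DESeq2 1.42.0 size factors and Wald test for counts, median centring and limma without trend for TPM, factors from genes off chromosomes 3 and 8, no filter or a mean level of at least 10, and pseudocount 0.1 or prior count 0.5. Others were a block for the replicate number, a minimum 2-fold change, a fit of the groups compared alone, and each library left out in turn. Summing RPF replicates 1 and 2 and leaving out several chromosomes with other shifted segments (7, 8, 10, 13, 18 and 22 in the chromosome 3 set, and 4, 10 and 20 in the chromosome 8 set) were chosen after seeing the data. Shifted windows on further chromosomes, such as 11 and 21 in the chromosome 3 set and 6 and 7 in the chromosome 8 set, stayed in. In RPF such windows lay on many further chromosomes, among them 1, 4, 5, 6 and 14.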

Results

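RNA and ribosome-protected fragments (RPF, the stretches of mRNA that a translating ribosome shields from nuclease) were sequenced from a human lung epithelial cell line and from isogenic derivatives that lost or gained a chromosome arm. The 21 libraries fell into 7 groups of 3. For chromosome 3, mRNA was measured in cells that lost 1 copy of the short arm (3p loss), in cells that gained a copy of the long arm (3q gain) and in cells with a normal chromosome 3 (WT). RPF were measured in 3p loss cells and in WT cells that the labels call 3p WT, where those of the mRNA are called chromosome 3 WT. For chromosome 8, mRNA was measured in 8p loss and WT cells. The replicates were biological replicates by the design text. Total counts were 7976310, 5630920 and 8521557 in the RPF WT libraries and 4622326, 5495204 and 13607875 in the RPF 3p loss libraries. The mRNA tables held values read as TPM (transcript abundance scaled to a fixed total). Their sums over protein-coding genes were 904850 to 916783 in the chromosome 3 set and 861114 to 881074 in the chromosome 8 set, and the depth behind them is unknown. Changes are log2 fold changes ± standard error, with n = 3 libraries per group throughout. TPM and CPM (counts scaled to library size) are means ± SD, and positions are on GRCh38. Adjusted p-values are Benjamini-Hochberg values from limma for mRNA and from edgeR for RPF, and gene lists were tested with camera.

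The comparison of 3p loss with WT mRNA asked how transcripts of the lost arm, and of the rest of the genome, stood in cells with a single 3p. Genes of 3p were lower almost throughout. The median over 321 tested 3p genes was -0.89, a fold of 0.541, with quartiles of -1.09 and -0.63, while 3q had a median of 0.06. RHOA, a small GTPase of the actin cytoskeleton (chromosome 3, 49359145 to 49411976), fell from 530.1 ± 6.31 to 288 ± 12.7 TPM (-0.88 ± 0.08, limma adjusted p = 0.00049). CTNNB1, which encodes beta-catenin (41199505 to 41240443), fell from 254 ± 23.3 to 102 ± 13.1 TPM (-1.32 ± 0.12, limma adjusted p = 0.00049). Other 3p genes with known roles in cancer fell by similar amounts. The deubiquitinase gene BAP1 changed by -0.81 ± 0.13 and the hypoxia regulator VHL by -0.92 ± 0.14. The phosphatase gene CTDSPL changed by -0.99 ± 0.14 and the nucleotide excision repair gene XPC by -1.55 ± 0.21. Limma adjusted p-values of these 4 genes ran from 0.00199 to 0.00341. TGFBR2 and PPARG had values of -1.08 ± 0.38 and -0.88 ± 0.52 and did not pass (limma adjusted p = 0.0843 and 0.28).

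Of the 321 tested 3p genes, limma called 228 lower and 1 higher. The mean level of the arm relative to other autosomes was -0.80 ± 0.036 in 3p loss and 0.07 ± 0.020 in WT libraries. This is a shift of -0.86 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). In camera the 3p genes were lower than the other genes with an adjusted p = 7.06e-54, and an adjusted p = 0.102 with an estimated correlation. As a share of the log2 change that 1 copy in place of 2 would give, the median was 0.886 (95% bootstrap interval 0.838 to 0.941). The mRNA shares here and below depend on the pseudocount, so their intervals alone do not show a departure from the copy number. A few 3p genes went far beyond the dose. The axon guidance receptor gene ROBO1 (78597239 to 79767998) fell from 16.5 ± 2.44 to 0.181 ± 0.0733 TPM (-3.88 ± 0.36). ROBO1 also fell in 3q gain mRNA, where 3p was unaltered, so its fall was not particular to 3p loss. The lipid raft protein gene RFTN1 changed by -3.49 ± 0.28, CMTM7 by -3.02 ± 0.23 and the receptor phosphatase gene PTPRG by -2.46 ± 0.25. The largest positive value on the arm belonged to the nuclear pore gene NUP210, at 2.08 ± 0.67, and did not pass (limma adjusted p = 0.0659).

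**Figure D1:**
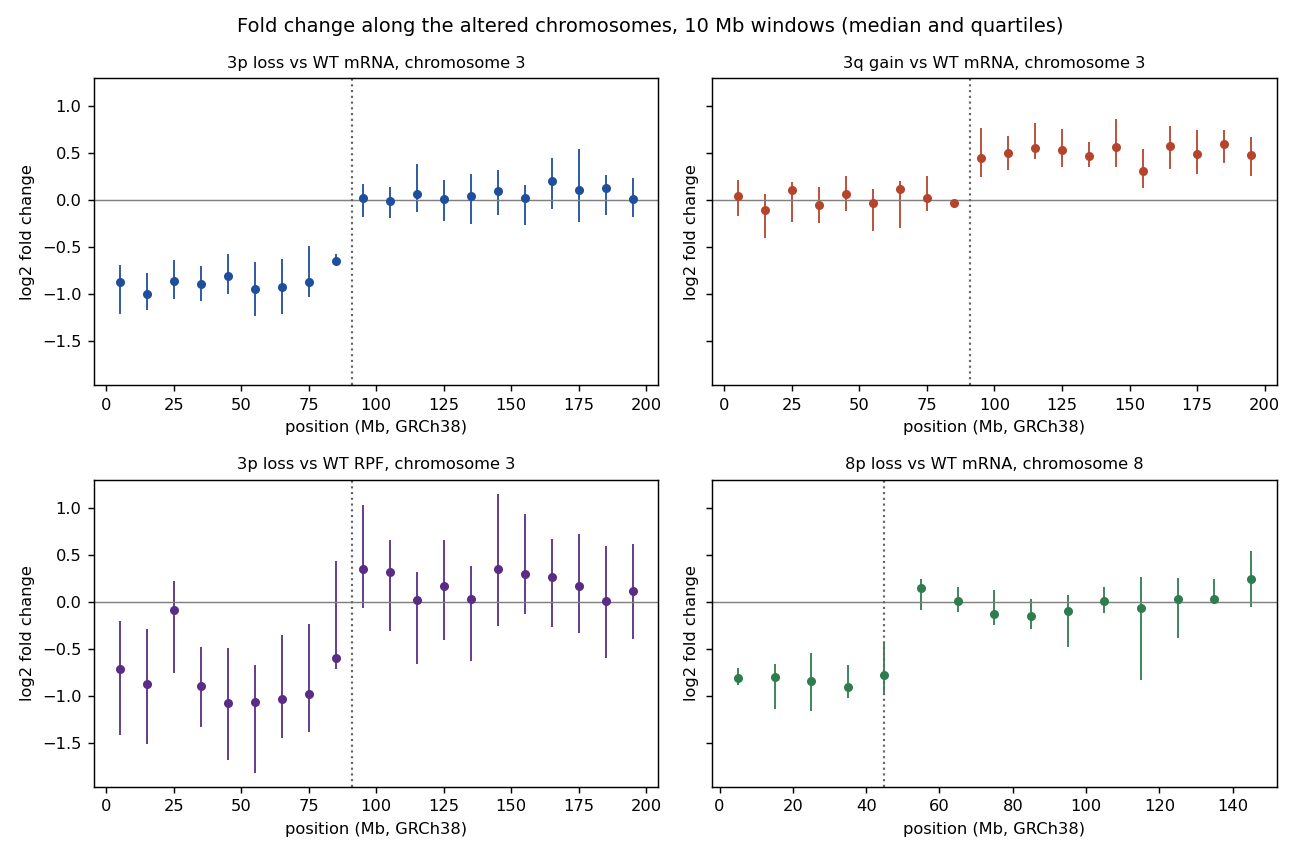
Median log2 fold change of tested genes in windows of 10 Mb (points, bars from the lower to the upper quartile) against position in Mb along the altered chromosome, in 3p loss mRNA, 3q gain mRNA, 3p loss RPF and 8p loss mRNA, each against WT, with a dotted line at the centromere. Windows on 3p in 3p loss mRNA lie at or below -0.65, while the medians over the unaltered arm of each mRNA comparison are 0.06 for 3q, 0.00 for 3p and 0.03 for 8q.

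Among the largest rises off chromosome 3 in 3p loss mRNA was the keratin gene KRT13, whose paralogs can share reads (6.43 ± 1.08, 452 ± 468 against 5.87 ± 8.76 TPM, limma adjusted p = 0.00462). Also high were ALPP, an alkaline phosphatase gene with close paralogs (4.89 ± 0.38, limma adjusted p = 0.000347), and MYH14, a nonmuscle myosin heavy chain gene (4.21 ± 0.56, limma adjusted p = 0.00176). ID2, an inhibitor of basic helix-loop-helix transcription factors (chromosome 2, 8682056 to 8684461), rose from 1.75 ± 0.598 to 64.9 ± 21.4 TPM (4.54 ± 0.38, limma adjusted p = 0.000391). Among the largest falls were the cyclin gene CCND2 (-5.24 ± 0.64, 0.0625 ± 0.0574 against 41.5 ± 16.0 TPM, limma adjusted p = 0.00122) and INHBA, the activin A subunit (-4.58 ± 0.30, limma adjusted p = 0.000242). CSF3, the granulocyte growth factor, fell as well (-4.31 ± 0.38, limma adjusted p = 0.000463), as did the calcium-binding protein gene S100A9 (-3.69 ± 0.55, limma adjusted p = 0.00267). In all, limma called 1681 of 11225 genes, 693 higher and 988 lower, of which 668 higher and 744 lower lay off the altered arms. The share called higher was 41.2%, and 56.8% of 1968 genes with median centring, which moved the median of all genes by 0.085. The count was 990.0 without 3p loss replicate 1 and 1062 without WT replicate 3, and 358 were higher and 775 lower without 3p loss replicate 3.

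Several groups of genes off the altered arms moved together in 3p loss mRNA, and camera called 15 of 30 lists, and 0 with an estimated correlation. Nuclear genes of oxidative phosphorylation rose, with a median of 0.46 over 58 genes (camera adjusted p = 2.53e-12, adjusted p = 0.23 with an estimated correlation). Of these, 26 were higher and 1 lower over all genes tested, and 35 higher and 1 lower adjusted over the list alone. The cytochrome c oxidase subunit gene COX7C rose by 0.71 ± 0.09 and the complex III gene UQCRH by 0.63 ± 0.10. Proteasome subunit genes rose, with a median of 0.40 over 30 genes (camera adjusted p = 3.49e-09, adjusted p = 0.392 with an estimated correlation). Limma called 16 of them higher over all genes, and 24 higher and 1 lower adjusted over the list alone. The proteasome gene PSMB1 rose by 1.01 ± 0.16. Cell cycle genes had a median of 0.37 over 37 genes (camera adjusted p = 3.38e-07, adjusted p = 0.597 with an estimated correlation). Among these, 7 were higher over all genes, with the mitotic activator CDC20 at 0.67 ± 0.13, and 13 adjusted over the list alone. Targets of the antioxidant factor NRF2 had a median of 0.45 over 30 genes (camera adjusted p = 0.00147, adjusted p = 0.444 with an estimated correlation). Over all genes 9 were higher, and 12 higher and 1 lower adjusted over the list alone. The ferritin heavy chain gene FTH1 stood at 1.27 ± 0.18 and the quinone reductase gene NQO1 at 0.66 ± 0.14. Interferon-response genes had a median of 0.63 over 49 genes (camera adjusted p = 0.000376, adjusted p = 0.63 with an estimated correlation). Limma called 6 of them over all genes and 0 adjusted over the list alone, with 19 at an unadjusted p under 0.05. The camera call of this list in 3p loss vs WT mRNA ended without 3p loss replicate 3 (limma and camera, adjusted p = 0.0882).

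Other groups fell in 3p loss mRNA. Targets of ATF4, the transcription factor of the integrated stress response, had a median of -1.19 over 27 genes (camera adjusted p = 1.48e-10, adjusted p = 0.444 with an estimated correlation). Limma called 18 lower over all genes and 22 lower adjusted over the list alone. ATF4 itself, which lies on 22q next to the shifted distal part, changed by -1.53 ± 0.17 and the mitochondrial folate enzyme gene MTHFD2 by -1.41 ± 0.22. Inflammatory NF-kappa-B targets had a median of -1.34 over 28 genes (camera adjusted p = 3.38e-07, adjusted p = 0.402 with an estimated correlation). Here 11 were lower over all genes and 14 adjusted over the list alone, including the cytokine genes IL1B (-3.05 ± 0.36) and IL1A (-3.66 ± 0.56). Targets of p53 had a median of -0.63 over 27 genes (camera adjusted p = 7.07e-07, adjusted p = 0.444 with an estimated correlation). The DNA damage recognition gene DDB2 (-1.03 ± 0.20) was among 12 that were lower over all genes and 13 adjusted over the list alone. Matrix and integrin genes had a median of -0.51 over 21 genes (camera adjusted p = 0.000124, adjusted p = 0.402 with an estimated correlation). They counted 8 lower and 1 higher over all genes and 11 lower and 1 higher adjusted over the list alone. The hyaluronan receptor gene CD44 stood at -1.35 ± 0.23.

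The comparison of 3q gain with WT mRNA asked the converse question, for an arm present in 3 copies. Genes of 3q were higher, with a median of 0.51 over 324 genes, a fold of 1.43, while 3p had a median of 0.00. MCM2, a subunit of the replicative helicase (chromosome 3, 127598411 to 127622436), rose from 107 ± 0.523 to 223 ± 12.2 TPM (1.05 ± 0.09, limma adjusted p = 0.00161). The translation initiation factor gene EIF4G1 (184314606 to 184335358) rose from 199 ± 11.4 to 319.8 ± 14.6 TPM (0.68 ± 0.09, limma adjusted p = 0.00646). The ADP-ribosyltransferase genes PARP9 and PARP14, which are also induced by interferon, rose by 2.47 ± 0.39 and 1.90 ± 0.32 (limma adjusted p = 0.0105 and 0.0131). Their calls ended without 3q gain replicate 3 (limma adjusted p = 0.0532 and 0.0648). Several 3q genes of interest in squamous cancers had values that did not pass. TP63, the basal cell transcription factor, stood at 0.21 ± 0.21 (limma adjusted p = 0.574). The kinase gene PIK3CA stood at 0.41 ± 0.18 (limma adjusted p = 0.197) and the transferrin receptor gene TFRC at 0.58 ± 0.20 (limma adjusted p = 0.12).

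Limma called 95 of the 324 tested 3q genes higher and 1 lower, while over the whole genome it called 35 genes higher without 3q gain replicate 3 and 55 without 3q gain replicate 2. The arm stood at 0.30 ± 0.046 relative to other autosomes in 3q gain and at -0.22 ± 0.025 in WT libraries, a shift of 0.52 (exact permutation p = 0.1, two-sided, the smallest possible). Camera placed 3q above other genes with an adjusted p = 1.2e-31, and an adjusted p = 0.321 with an estimated correlation. As a share of the log2 change for 3 copies in place of 2, the median was 0.8799 (95% bootstrap interval 0.827 to 0.940). The difference from the share for 3p loss was 0.0066 (95% interval -0.0673 to 0.0788), so a difference between loss and gain was not detected in mRNA. That interval draws genes, which are not independent replicates, and leaves out the spread between libraries and the shared WT libraries. The SD of the share between libraries was 0.0817 in 3p loss and 0.148 in 3q gain, so the interval overstates the precision. On 3q, 17 genes that encode subunits of large complexes had a median of 0.66 against 0.51 for the other genes (permutation p = 0.121, two-sided, Benjamini-Hochberg adjusted p = 0.482 over 4 such tests). On 3p in 3p loss mRNA, 11 complex genes had a median of -0.97 against -0.89 (permutation p = 0.5002). With ribosomal proteins left out, the direction turned, with 6 complex genes at -0.54 against -0.89 (permutation p = 0.0482, Benjamini-Hochberg adjusted p = 0.193 over 4 such tests).

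**Figure D2:**
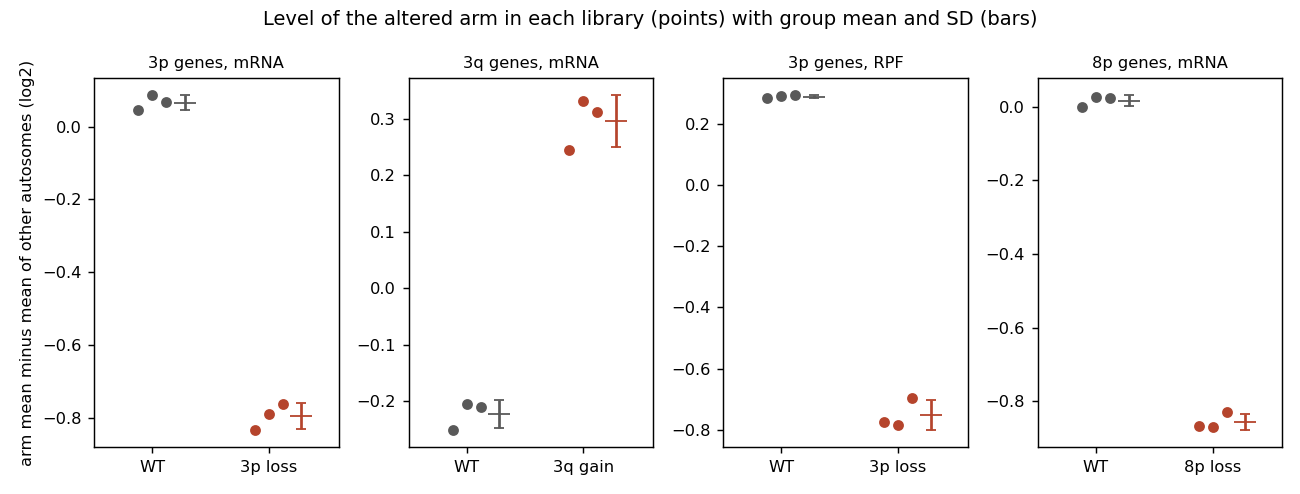
Mean log2 level of the altered arm minus the mean of the other autosomes in each library (points), with the group mean and SD (bars), for 3p and 3q in chromosome 3 mRNA, 3p in RPF and 8p in chromosome 8 mRNA. The means are -0.80 in 3p loss and 0.07 in WT for 3p mRNA, and the groups of each comparison do not overlap on the altered arm.

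Off the altered arm, interferon-response genes had the highest median of the 30 lists in 3q gain, at 1.34 over 49 genes (camera adjusted p = 4.12e-16, adjusted p = 0.385 with an estimated correlation). Limma called 11 higher over all genes and 32 higher adjusted over the list alone. The antiviral GTPase gene MX1 rose by 4.03 ± 0.73 (107 ± 65.4 against 4.86 ± 2.12 TPM, limma adjusted p = 0.0178) and the interferon-induced gene IFI6 by 3.77 ± 0.64 (502 ± 313 against 32.3 ± 11.1 TPM, limma adjusted p = 0.0139). Both calls ended without 3q gain replicate 3 (limma adjusted p = 0.0797 and 0.0602), and that of MX1 also without WT replicate 2 (limma adjusted p = 0.0566). MYH14 was higher (3.85 ± 0.56, limma adjusted p = 0.0083), as were the angiomotin gene AMOT (3.49 ± 0.47, limma adjusted p = 0.00667) and HLA-DQB1, an antigen presentation gene with close paralogs (3.43 ± 0.43, limma adjusted p = 0.00498). KRT14, a basal cell keratin with close paralogs (chromosome 17, 41582279 to 41586895), fell from 1379.2 ± 673 to 55.0 ± 38.8 TPM (-4.91 ± 0.84, limma adjusted p = 0.0143). CSF3 changed by -4.37 ± 0.38, INHBA by -4.20 ± 0.30 and the branched-chain amino acid transaminase gene BCAT1 by -3.63 ± 0.35. ROBO1, although on the unaltered 3p, fell in 3q gain as well (-3.36 ± 0.36, limma adjusted p = 0.00287).

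ATF4 targets were lower in 3q gain too, with a median of -1.06 over 27 genes (camera adjusted p = 9.29e-13, adjusted p = 0.385 with an estimated correlation). Limma called 11 lower over all genes and 19 adjusted over the list alone, and ATF4 stood at -1.49 ± 0.17. Targets of p53 had a median of -0.53 over 27 genes (camera adjusted p = 1.32e-07, adjusted p = 0.385 with an estimated correlation), with 7 lower over all genes and 14 adjusted over the list alone. NF-kappa-B targets had a median of -0.89 over 28 genes (camera adjusted p = 1.32e-07, adjusted p = 0.385 with an estimated correlation), with 8 lower over all genes and 12 adjusted over the list alone. Genes of the TGF-beta and mesenchymal list had a median of -0.59 over 31 genes (camera adjusted p = 2.32e-05, adjusted p = 0.385 with an estimated correlation). The inhibitory SMAD gene SMAD7 (-1.08 ± 0.15) was among 6 that were lower over all genes and 10 adjusted over the list alone. Oxidative phosphorylation genes had a median of 0.14 over 58 genes (camera adjusted p = 0.000461, adjusted p = 0.385 with an estimated correlation). Of them 4 were higher and 1 lower over all genes, and 12 higher and 1 lower adjusted over the list alone. Limma called 592 of 11225 genes in 3q gain, 292 higher and 300 lower, with 2591 at an unadjusted p under 0.05. This count rested on few libraries. It was 110 without 3q gain replicate 3, 149 without 3q gain replicate 2, 273 without WT replicate 2 and 294 without WT replicate 3. The balance moved as well, with 35 higher and 75 lower without 3q gain replicate 3 and 402 and 276 with factors from genes off chromosomes 3 and 8.

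The genes that moved in 3p loss and in 3q gain overlapped although the altered arms differ. CSF3, INHBA and ROBO1 fell and MYH14 rose in both. Off chromosomes 3 and 8, the fold changes correlated across 9838 genes with Pearson r = 0.73 and Spearman rho = 0.73, with genes not being independent replicates. Both comparisons used the same WT libraries, and simulated data with no effect gave r = 0.50 (SD 0.016) from that sharing alone. Limma called 127 genes higher in both, 232 lower in both and 0 in opposite directions. Without 3q gain replicate 3, limma called 35 genes higher and 75 lower in 3q gain, so the overlaps could be no larger than that. Independent lists, without shared WT libraries, would give 11.4, 19.8 and 30.4, and 50 simulated sets with shared WT libraries and no effect gave 0 each. Neither value holds both the effects and the sharing, so part of the excess may come from the shared WT libraries. The covariance of the fold changes was 0.248, against 0.0438 in the simulated data.

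Set directly against 3q gain, 3p loss mRNA differed on both arms. The 3p genes had a median of -0.84 (camera adjusted p = 8.54e-97, adjusted p = 0.0218 with an estimated correlation) and the 3q genes of -0.49 (camera adjusted p = 2.59e-37, adjusted p = 0.206 with an estimated correlation). CMTM7 (-2.67 ± 0.23, limma adjusted p = 0.000969) and the circadian repressor gene BHLHE40 (-1.90 ± 0.18, limma adjusted p = 0.00116), both on 3p, were lower in 3p loss. RHOA (-0.92 ± 0.08) and CTNNB1 (-1.43 ± 0.12) were lower as well, both with a limma adjusted p = 0.000969. Higher in 3p loss were ALPP (4.15 ± 0.38) and ID2 (4.13 ± 0.38), with the same adjusted p. The epidermal keratin gene KRT1 (4.01 ± 0.43, limma adjusted p = 0.00174) and the basement membrane gene NID1 (3.90 ± 0.41, limma adjusted p = 0.00168) were also higher. Squamous differentiation genes had a median of 0.71 over 20 genes (camera adjusted p = 0.000833, adjusted p = 0.81 with an estimated correlation). KRT10 (2.05 ± 0.27) was among 4 that were higher over all genes and 4 adjusted over the list alone. Oxidative phosphorylation genes were higher by a median of 0.25 over 58 genes (camera adjusted p = 8.29e-13, adjusted p = 0.21 with an estimated correlation). Limma called 0 of these over all genes and 8 adjusted over the list alone, with 21 at an unadjusted p under 0.05. Interferon-response genes were lower by a median of -0.73 over 49 genes (camera adjusted p = 1.93e-09, adjusted p = 0.81 with an estimated correlation). Limma called 0 of these over all genes and 0 adjusted over the list alone, with 10 at an unadjusted p under 0.05. ATF4 targets had a median of -0.046 over 27 genes and did not differ between 3p loss and 3q gain past the threshold (limma and camera, adjusted p = 0.57).

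Limma called 441 of 11225 genes in this direct contrast, 98 higher and 343 lower, and 258 of the 645 tested genes on both arms were lower with 0 higher. The count was 191 without 3p loss replicate 1, 226 without 3q gain replicate 1, 187 without 3q gain replicate 2 and 235 without 3q gain replicate 3, with 34, 29, 41 and 46 of these higher. With a block for the replicate number it was 351, and same-numbered libraries of 3p loss and 3q gain were closer than others (r from 0.12 to 0.16 after removal of group means).

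Ribosome-protected fragments in 3p loss and WT cells asked whether the lower transcript dose of 3p was matched at the ribosome. Footprints of 3p genes were lower, with a median of -1.01 over 324 genes, a fold of 0.496. RHOA fell from 286 ± 45.3 to 135 ± 3.95 CPM (-1.09 ± 0.11, edgeR adjusted p = 2.98e-06), and CTNNB1 from 893 ± 50.2 to 439.6 ± 22.7 CPM (-1.02 ± 0.08, edgeR adjusted p = 3.65e-07). BAP1 (52401008 to 52410008) fell from 222 ± 44.97 to 51.0 ± 10.9 CPM (-2.10 ± 0.17, edgeR adjusted p = 3.5e-07). TGFBR2, a receptor for TGF-beta, changed by -2.57 ± 0.10 (edgeR adjusted p = 1.5e-09). VHL (10141778 to 10153667) stood at 79.0 ± 26.6 against 79.2 ± 3.90 CPM (0.02 ± 0.18, edgeR adjusted p = 0.933). Its value was -0.31 (edgeR adjusted p = 0.0137) without RPF 3p loss replicate 3. Some 3p genes had more footprints in 3p loss, among them VILL, a villin-like gene (1.90 ± 0.24, edgeR adjusted p = 1.57e-05), and the initiation factor paralog EIF1B (1.39 ± 0.17, edgeR adjusted p = 1.37e-05). EPHA3, an ephrin receptor gene near the centromere (89107621 to 89482134), had 440 counts over the 3p loss libraries and 0 over the WT libraries. This is at least 123.5-fold higher against a floor of 3 counts over the group. Floors and counting intervals cover counting error only.

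EdgeR called 7913 of 11425 genes in RPF, 4006 higher and 3907 lower, and 246 of the 324 tested 3p genes were lower and 13 higher. The arm stood at -0.75 ± 0.049 in RPF 3p loss and 0.29 ± 0.0048 in RPF WT libraries relative to other autosomes, a shift of -1.04 (exact permutation p = 0.1, two-sided, the smallest possible). The camera adjusted p = 1.83e-16, and the adjusted p = 0.0615 with an estimated correlation. As a share of the change for 1 copy in place of 2, the median was 1.01 (95% bootstrap interval 0.866 to 1.08). Complex subunit genes on 3p had a median of -0.70 against -1.03 for other 3p genes (permutation p = 0.256, two-sided, Benjamini-Hochberg adjusted p = 0.5002). Replicates 1 and 2 of each RPF group were closer to each other than other pairs. Their chi-square per degree of freedom was 1.31 in WT and 1.35 in 3p loss, against 6.77 to 12.0 for pairs with replicate 3, and edgeR called 6797 genes with them summed. The RPF p-values take the 3 libraries of a group as independent, and replicates 1 and 2 may not be.

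Among all genes, the footprint changes were wide. VIM, the mesenchymal intermediate filament vimentin (chromosome 10, 17228241 to 17237593), fell from 357 ± 4.93 to 2.94 ± 0.458 CPM (-6.84 ± 0.14, edgeR adjusted p = 4.34e-12). Its mRNA varied widely between replicates, at 161 ± 136 TPM in WT and 70.8 ± 103 TPM in 3p loss. CSF3 had 0 counts over the 3p loss libraries and 352 over the WT libraries, at least 139-fold lower against the same floor. ROBO1 changed by -5.64 ± 0.25 (edgeR adjusted p = 2.54e-09). KRT13 rose by 7.60 ± 0.20 (95.6 ± 3.54 against 0.485 ± 0.0824 CPM, edgeR adjusted p = 5.62e-11) and AMOT by 6.46 ± 0.20 (edgeR adjusted p = 2.39e-10). FREM2, an extracellular matrix gene, had 647 counts against 1, a ratio of 545 (95% counting interval 97.4 to 21553).

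Camera called 16 of 33 lists in RPF, and 0 with an estimated correlation. Interferon-response genes were higher by a median of 1.89 over 42 genes (camera adjusted p = 1.75e-12, adjusted p = 0.134 with an estimated correlation). EdgeR called 37 higher and 2 lower, over all genes and adjusted over the list alone, with the ubiquitin-like ISG15 at 3.60 ± 0.15. Oxidative phosphorylation genes were higher by 0.90 over 64 genes (camera adjusted p = 2.39e-09, adjusted p = 0.275 with an estimated correlation). EdgeR called 51 of these higher and 2 lower, over all genes and adjusted over the list alone, with COX4I1 at 1.24 ± 0.11. The 13 protein genes of the mitochondrial genome went the other way, with a median of -2.14 (camera adjusted p = 9.41e-07, adjusted p = 0.321 with an estimated correlation). All 13 were lower over all genes and adjusted over the list alone, MT-CO1 by -1.55 ± 0.15 and MT-ND6 by -2.64 ± 0.09. Mitochondrial genes held 1.597 to 1.73% of the counts in WT and 0.380 to 0.690% in 3p loss libraries. Ribosomal protein genes were higher by 0.62 over 56 genes (camera adjusted p = 9.41e-07, adjusted p = 0.242 with an estimated correlation). They counted 46 higher and 3 lower over all genes and 47 and 4 adjusted over the list alone. RPS3 rose by 1.46 ± 0.08, and RPL3, on 22q next to the shifted distal part, changed by -0.91 ± 0.07.

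ATF4 targets, lower in mRNA, were higher in RPF, with a median of 0.77 over 34 genes (camera adjusted p = 6.97e-06, adjusted p = 0.134 with an estimated correlation). The alanyl-tRNA synthetase gene AARS1 (1.90 ± 0.08) was among 27 higher, with 3 lower, over all genes and adjusted over the list alone. Chaperones of the endoplasmic reticulum had a median of 0.79 over 19 genes (camera adjusted p = 0.00021, adjusted p = 0.242 with an estimated correlation). The luminal chaperone HSPA5 (1.25 ± 0.08) was among 14 higher, with 1 lower, over all genes and adjusted over the list alone. Cholesterol and fatty acid synthesis genes were lower by -1.20 over 30 genes (camera adjusted p = 1.01e-06, adjusted p = 0.191 with an estimated correlation). EdgeR called 22 of these lower and 3 higher, over all genes and adjusted over the list alone, with the fatty acid synthase gene FASN at -3.14 ± 0.13. Matrix and integrin genes were lower by -1.11 over 21 genes (camera adjusted p = 1.45e-05, adjusted p = 0.134 with an estimated correlation). The cytolinker gene PLEC (-2.21 ± 0.11) was among 17 lower, with 3 higher, over all genes and adjusted over the list alone. Targets of p53 had a median of 0.44 over 27 genes (camera adjusted p = 0.042, adjusted p = 0.242 with an estimated correlation), with 15 higher and 4 lower over all genes and 16 and 4 adjusted over the list alone. This last call in 3p loss vs WT RPF ended without RPF WT replicate 1 and without RPF WT replicate 2 (edgeR and camera, adjusted p = 0.0533 and 0.0506). It also ended with RPF replicates 1 and 2 summed, with the altered arms kept in and without several chromosomes with other shifted segments (edgeR and camera, adjusted p = 0.0671, 0.0569 and 0.188).

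**Figure D3:**
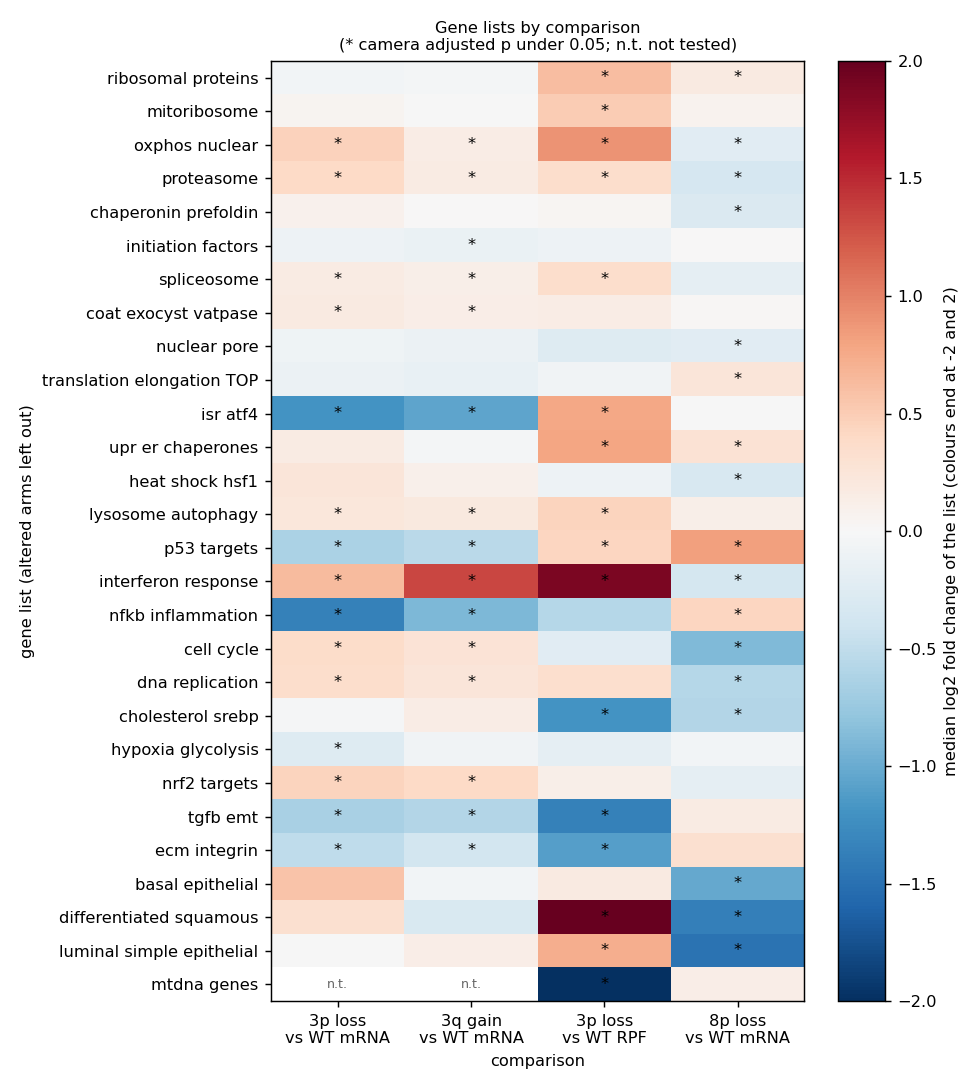
Median log2 fold change of each gene list (vertical axis) in 4 comparisons (horizontal axis), as a colour scale, with an asterisk for a camera adjusted p under 0.05 with the preset correlation and n.t. for a list not tested. Interferon-response genes stand at 0.63 in 3p loss mRNA, 1.34 in 3q gain mRNA, 1.89 in 3p loss RPF and -0.35 in 8p loss mRNA.

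The difference between the RPF and the mRNA change of 3p loss, a measure of translational efficiency, asked whether translation of 3p genes or of other groups shifted beyond their mRNA. For 3p genes the median difference was -0.10 over 297 genes (limma and camera, adjusted p = 0.857), with 50 genes higher and 59 lower by limma. On the arm, EIF1B (2.04 ± 0.30, limma adjusted p = 0.000463) and VHL (0.87 ± 0.25, limma adjusted p = 0.0176) were higher. The footprint value of VHL depended on RPF 3p loss replicate 3, as given above. BAP1 (-1.29 ± 0.24, limma adjusted p = 0.0014) and NUP210 (-3.22 ± 0.63, limma adjusted p = 0.00193) were lower. RHOA had a value of -0.19 ± 0.16 and CTNNB1 of 0.30 ± 0.16, neither past the threshold (limma adjusted p = 0.368 and 0.165). Across the genome the largest rises included NUPR1, a stress-induced chromatin protein gene (4.97 ± 0.53, limma adjusted p = 7.08e-05), and the stress cytokine gene GDF15 (4.67 ± 0.72, limma adjusted p = 0.000551). They also included the glutathione-degrading CHAC1 (3.81 ± 0.70, limma adjusted p = 0.00137) and the serine synthesis gene PSAT1 (3.73 ± 0.54, limma adjusted p = 0.000413). The largest falls included FGFBP1, a carrier of fibroblast growth factors (-3.85 ± 0.38, limma adjusted p = 3.85e-05), and the transglutaminase gene TGM2 (-3.80 ± 0.63, limma adjusted p = 0.000782). The mRNA and RPF libraries were separate samples, with WT libraries of different labels, so these differences hold any difference between the cultures as well as translation.

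ATF4 targets led the lists of this difference, with a median of 2.11 over 26 genes (camera adjusted p = 1.47e-10, adjusted p = 0.398 with an estimated correlation). Limma called 23 higher and 1 lower, over all genes and adjusted over the list alone, with the serine synthesis gene PHGDH at 2.61 ± 0.31. Targets of p53 had a median of 0.91 over 26 genes (camera adjusted p = 1.37e-05, adjusted p = 0.419 with an estimated correlation). The cell cycle inhibitor CDKN1A (2.13 ± 0.33) and the p53 ligase gene MDM2 (1.89 ± 0.39) were among 18 higher, with 2 lower, over all genes and adjusted over the list alone. Ribosomal protein genes were higher by 0.63 over 56 genes (camera adjusted p = 1.47e-10, adjusted p = 0.134 with an estimated correlation). RPS19 (1.16 ± 0.18) was among 40 higher, with 2 lower, over all genes, and 46 and 2 adjusted over the list alone. Cholesterol and fatty acid synthesis genes were lower by -1.18 over 30 genes (camera adjusted p = 2.34e-09, adjusted p = 0.134 with an estimated correlation), FASN by -3.01 ± 0.25, with 21 lower over all genes and 22 adjusted over the list alone. Cell cycle genes were lower by -0.67 over 37 genes (camera adjusted p = 3.14e-06, adjusted p = 0.594 with an estimated correlation). The topoisomerase gene TOP2A (-1.15 ± 0.20) was among 19 lower over all genes and 21 adjusted over the list alone. Limma called 3651 of 10142 genes, 1840 higher and 1811 lower, and 2065 with RPF replicates 1 and 2 summed. With median centring of TPM and DESeq2 size factors for RPF, 1595 were higher and 2183 lower. Off chromosomes 3 and 8, the mRNA and RPF changes of 3p loss correlated across 8907 genes with r = 0.55 and rho = 0.43. In both assays 403 genes were higher and 449 lower, where chance gives 198 and 214, and 120 were called in opposite directions, where chance gives 414.

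Loss of 8p was measured in a separate set of libraries and asked whether another lost arm behaved like 3p. Genes of 8p were lower, with a median of -0.83 over 146 genes, a fold of 0.564, and 8q had a median of 0.03. CLU, which encodes the extracellular chaperone clusterin (chromosome 8, 27596917 to 27614700), fell from 79.4 ± 2.67 to 10.6 ± 0.555 TPM (-2.79 ± 0.05, limma adjusted p = 1.41e-07). NRG1, the growth factor neuregulin (31639245 to 32774046), fell from 9.99 ± 0.290 to 1.63 ± 0.0840 TPM (-2.06 ± 0.06, limma adjusted p = 6.56e-07). The phosphatase subunit gene PPP2R2A changed by -1.07 ± 0.03 and the oligosaccharyltransferase gene TUSC3 by -1.36 ± 0.05. The cathepsin gene CTSB changed by -0.71 ± 0.03 and the death receptor gene TNFRSF10B by -0.64 ± 0.03. Limma adjusted p-values of these 4 genes ran from 7.1e-07 to 2.75e-06. Against the dose, FAM167A rose by 1.30 ± 0.08 (limma adjusted p = 1.31e-05).

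Limma called 132 of the 146 tested 8p genes lower and 2 higher. The arm stood at -0.86 ± 0.022 in 8p loss and 0.02 ± 0.015 in WT libraries, a shift of -0.87 (exact permutation p = 0.1, two-sided, the smallest possible). The camera adjusted p = 8.63e-21, and the adjusted p = 0.13 with an estimated correlation. The share of the change for 1 copy in place of 2 was 0.827 (95% bootstrap interval 0.789 to 0.933), and 3p loss mRNA exceeded it by 0.0591 (95% interval -0.0523 to 0.123). With means in place of medians the order turned, with shares of 0.854 in 3p loss mRNA and 0.886 in 8p loss. Across the genome limma called 8498 of 12302 genes, 4070 higher and 4428 lower, 1259 of them by at least 2-fold. Replicates of this set were close to each other, with correlations of 0.987 to 0.993 between libraries of a group, against 0.953 to 0.981 in the chromosome 3 mRNA set. Parts of chromosomes 4, 10 and 20 were also shifted in this set. Medians were -0.75 for the first 10 Mb of chromosome 4, 0.79 for 10p and -0.78 for 30 to 40 Mb of chromosome 20. Windows further along chromosome 4 were as low as 8p, whose median was -0.83. Examples are -0.83 for 80 to 90 Mb, -0.99 for 130 to 140 Mb and -0.86 for 180 to 190 Mb.

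The largest changes in 8p loss lay off the arm. TERT, the catalytic subunit of telomerase (chromosome 5, 1253167 to 1295068), stood at 147 ± 17.7 TPM in 8p loss and 1.29 ± 0.289 TPM in WT libraries (6.01 ± 0.12, limma adjusted p = 1.82e-07). In the chromosome 3 set it stood at 185 ± 52.0 TPM in WT, 118 ± 20.5 TPM in 3p loss and 202 ± 44.5 TPM in 3q gain libraries. The 8p WT libraries thus stood apart in TERT from every other mRNA group. With the shifted parts of chromosomes 4, 10 and 20, the 8p loss and 8p WT cultures may differ in more than the arm. Changes off 8p therefore cannot be tied to its loss here. IL1RL1, the receptor for interleukin 33, rose by 4.29 ± 0.04 (limma adjusted p = 2.02e-08) and the collagenase gene MMP1 by 4.14 ± 0.07 (limma adjusted p = 1.13e-07). VIM, on the shifted 10p, rose from 51.5 ± 1.12 to 505 ± 51.1 TPM (3.27 ± 0.07, limma adjusted p = 2.42e-07). The phosphatase regulator gene PPP1R16B (chromosome 20, 38805697 to 38923024) changed by -6.07 ± 0.06 (limma adjusted p = 2.02e-08). The myosin light chain gene MYL9 (chromosome 20, 36541519 to 36551447) changed by -4.30 ± 0.07 (limma adjusted p = 1.41e-07), and both lie in the shifted part of chromosome 20. ZFP42 on distal chromosome 4, which was also shifted, a zinc finger gene of pluripotent cells, changed by -5.70 ± 0.09 (limma adjusted p = 1.07e-07). The kallikrein gene KLK5 changed by -4.82 ± 0.14 (limma adjusted p = 5.06e-07).

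Camera called 17 of 32 lists in 8p loss, and 0 with an estimated correlation. All 38 tested cell cycle genes were lower, over all genes and adjusted over the list alone, with a median of -0.89 (camera adjusted p = 1.55e-14, adjusted p = 0.118 with an estimated correlation). The spindle gene TPX2, on chromosome 20, stood at -1.34 ± 0.03 and CDC20 at -0.41 ± 0.04. Targets of p53 were higher by a median of 0.82 over 29 genes (camera adjusted p = 1.23e-08, adjusted p = 0.0738 with an estimated correlation). CDKN1A (1.26 ± 0.03) and MDM2 (1.07 ± 0.04) were among 27 higher, with 2 lower, over all genes and adjusted over the list alone. Basal epithelial markers were lower by -1.03 over 22 genes (camera adjusted p = 2.31e-08, adjusted p = 0.0738 with an estimated correlation), KRT5 by -1.81 ± 0.03, with 21 lower and 1 higher over all genes and adjusted over the list alone. Luminal markers were lower by -1.47 over 21 genes (camera adjusted p = 1.33e-08, adjusted p = 0.0913 with an estimated correlation), the adhesion gene CDH1 by -2.39 ± 0.03, with 19 lower over all genes and adjusted over the list alone. Cholesterol and fatty acid synthesis genes were lower by -0.58 over 31 genes (camera adjusted p = 1.33e-08, adjusted p = 0.118 with an estimated correlation). The desaturase gene SCD (-1.36 ± 0.02) was among 27 lower, with 1 higher, over all genes and adjusted over the list alone. Ribosomal protein genes were higher by 0.18 over 79 genes (camera adjusted p = 5.19e-05, adjusted p = 0.491 with an estimated correlation), with 53 higher and 8 lower over all genes and adjusted over the list alone. Interferon-response genes had a median of -0.35 over 54 genes (camera adjusted p = 0.0149, adjusted p = 0.4 with an estimated correlation). They counted 33 lower and 15 higher over all genes and 34 and 15 adjusted over the list alone. In 8p loss vs WT mRNA this last call ended when several chromosomes with other shifted segments were left out (limma and camera, adjusted p = 0.128). Off chromosomes 3 and 8, the fold changes of 8p loss and 3p loss mRNA correlated across 9507 genes with r = -0.28 and rho = -0.26. With an estimated correlation, camera called 0 lists in each of the 6 comparisons. At an unadjusted p under 0.05 that test gave 3 lists in 3p loss mRNA, 1 in 3q gain, 1 in their direct contrast, 4 in RPF, 3 in translational efficiency and 8 in 8p loss.

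Regions outside the named arms also differed between the chromosome 3 groups. Genes on distal 22q, from 40 Mb on, were lower than in WT in 3p loss mRNA (median -0.84, 78 of 85 genes), in 3q gain mRNA (-0.87, 82 of 85) and in 3p loss RPF (-1.14, 76 of 84). Proximal 22q had medians of 0.07, 0.03 and -0.20. The splicing gene PHF5A lies in distal 22q, while ATF4 and RPL3 lie on 22q shortly before 40 Mb. PHF5A stood at -0.96 ± 0.13 in 3p loss and -0.99 ± 0.13 in 3q gain mRNA. In RPF, 10p, which carries VIM, had a median of -0.91, and the first 20 Mb of chromosome 8 had a median of 1.05. Other segments were shifted too. In RPF, windows with medians beyond 0.4 in either direction lay on many chromosomes. Examples are 0.70 for 80 to 90 Mb of chromosome 1, 0.84 for 20 to 30 Mb of chromosome 6 and -0.75 for 70 to 80 Mb of chromosome 18. The RPF windows from 90 to 120 Mb of chromosome 13 had medians of -0.70, -1.13 and -1.08, and 70 to 80 Mb of chromosome 11 of 0.75. In mRNA, 20 to 30 Mb of chromosome 21 had a median of -0.96 in 3p loss and -0.97 in 3q gain, over 10 genes. Single mRNA libraries of the chromosome 3 set departed from their group by over 0.4 on 10 arm values. Examples are 18p in WT replicate 1 (1.28), 10p in 3p loss replicate 2 (1.00) and WT replicate 2 (-0.81) and 10q in WT replicate 2 (-0.86). No RPF or chromosome 8 library departed by more than 0.253.

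**Figure D4:**
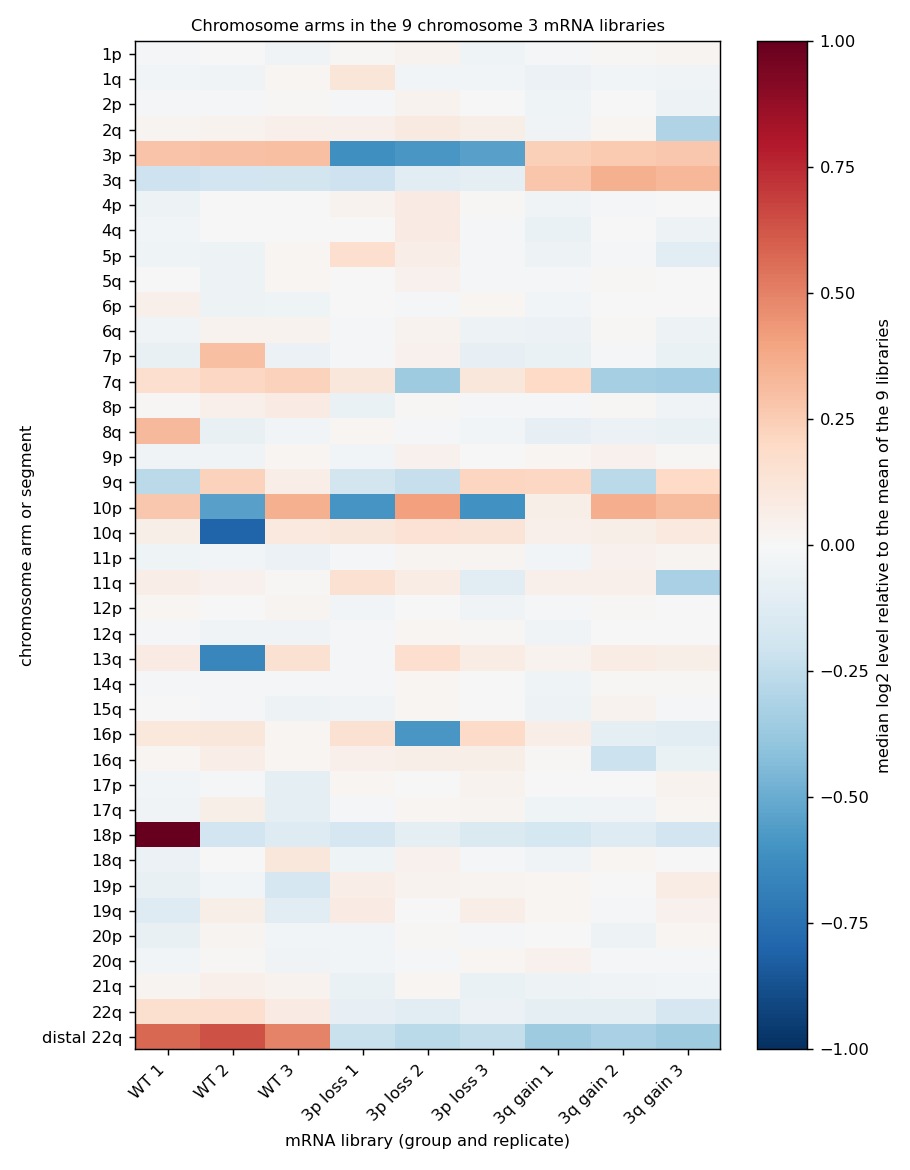
Median log2 level of the genes of each chromosome arm, relative to the mean of the 9 libraries, in each chromosome 3 mRNA library, as a colour scale with arms on one axis and libraries on the other, and with distal 22q shown on its own. Arms 3p, 3q and distal 22q follow the groups, and single libraries stand apart on others, such as WT replicate 1 on 18p at 1.28 from the median of its group.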

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

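Apart from the interaction tests of genes and gene lists and the counts of other splits of the libraries, the tests weighed in this part were chosen only after the results were seen.

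The change of 3p loss against WT differed between RPF and mRNA, by the interaction test, for 3 chromosome arms and 13 of 30 gene lists, of which 2 are given here. With an estimated correlation it called 0 lists and 0 arms. Genes of 7q had a median difference of 0.35, genes of 8p of 0.44 and genes of 10p of -0.68. Targets of ATF4 had a median difference of 2.11 and p53 targets of 0.91 (camera, adjusted p = 0.398 and 0.419 with an estimated correlation).

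Genes of 8p and 10p had different changes in RPF and in mRNA, where the WT libraries also carry different labels, 3p WT in RPF and chromosome 3 WT in mRNA. In RPF the first 20 Mb of chromosome 8 stood above the part from 120 Mb by 1.70. This argues against a single factor of scaling or depth per RPF library, which moves both ends of a chromosome alike. The ends were chosen after the results were seen. Library effects that differ between regions were not tested, and shifted windows lay on many other chromosomes in RPF. A candidate explanation is other chromosome content in the cultures used for RPF. In RPF 91.3% of the genes in the first 20 Mb of chromosome 8 were higher, which is part of the pattern itself and no separate support. Translation of 10p genes also stays open. The 10p interaction of -0.68 was nearest to 0, at -0.35, when 1 mRNA library (3p loss replicate 2) was left out. It was -0.41 without WT replicate 2. These mRNA libraries stood apart on 10p from their groups by 1.00 and -0.81, so part of the interaction came from single mRNA libraries. They were not left out together, so what would remain of the interaction is unknown. The median of 10p mRNA was -0.51 in 3p loss against 3q gain. These explanations cannot be told apart here, because the mRNA and RPF libraries were separate samples and no DNA was measured.

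Targets of ATF4 were lower in mRNA and higher in RPF of 3p loss. Their mRNA median of -1.19 argues against translational induction alone, which would leave mRNA at 0 or above. That value is part of the pattern itself and not a separate test. A single WT mRNA library was argued against by a median of -0.98, at its nearest to 0, with 1 WT library left out. The median of -0.046 between 3p loss and 3q gain mRNA goes with a state of the WT mRNA cultures that both altered genotypes lack. The WT mRNA cultures may therefore have had an active stress response. Such a state does not account for the rise in RPF, which had its own WT libraries. There the list had a median of 0.77 over 34 genes, with 27 higher and 3 lower. ATF4 itself lies on 22q next to the distal part, which was lower in both altered genotypes. A median near 0 between them does not set apart an effect of that part, which was not tested. A response of both altered genotypes remains a biological explanation that these libraries did not test.

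Distal 22q was lower in 3p loss and in 3q gain than in WT. The difference between distal and proximal 22q of -0.91 in 3p loss mRNA argues against a single scaling factor per library, which moves both parts alike. The parts were chosen after the results were seen, and library effects that differ between regions were not tested. A median of -0.80, at its nearest to 0 with 1 mRNA library left out, argues against a single WT library. A candidate explanation is another copy number of distal 22q in the WT cultures, or in the cells from which both altered genotypes came, and 90.5% of its genes were lower in 3p loss RPF as well. This stays open, since DNA was not analysed here. No biological explanation was tested.

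Other splits of the same libraries were counted for each test across genes. With 3 libraries against 3, 10 splits are too few for a share under 0.05, and the real split was the 1 with as many called genes in each of these comparisons. It gave 1681 genes in 3p loss mRNA against at most 10 in another split, 592 in 3q gain against 0, and 441 in their direct contrast against 24. It gave 7913 in RPF against 0 and 8498 in 8p loss against 0. For translational efficiency, 4 of 100 splits drawn gave at least the 3651 genes of the real one, which counts among them, and the highest other gave 4090. The 95% interval of that share, 1.10 to 9.93%, spans 5%, the share depends on which splits are drawn, and it passed 5% in another draw, so chance was not excluded. All 4 were among the 11 splits that kept the RPF groups whole, and splits that parted them gave at most 0 genes, so the count rested on the RPF groups.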

How the results depend on the processing

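Summing RPF replicates 1 and 2 and leaving out several chromosomes with other shifted segments were chosen only after the results were seen. Of 255 alternative values for the counts, arm shifts, lists and correlations, 215 stayed close to the reported value and 40 moved, while 0 were labelled as changed in direction. That label does not show the balance of called genes. In 3p loss mRNA the share called higher went from 41.2% to 56.8% with median centring. The difference between complex and other 3p genes in 3p loss mRNA turned as well, as given below. Each alternative kept the direction of the 4 arm shifts.

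A minimum 2-fold change removes smaller changes by construction and left 759 genes in 3p loss mRNA, 303 in 3q gain, 206 in their direct contrast, 3442 in RPF, 1841 in translational efficiency and 1259 in 8p loss. Without several chromosomes with other shifted segments, fewer genes were tested and 382 were called in 3q gain, 227 higher and 155 lower. Summing RPF replicates 1 and 2 left fewer libraries and 2065 genes in translational efficiency. With a block for the replicate number the counts were 1509, 451, 351, 7980, 3549 and 8456 in the same order. Same-numbered libraries of different groups correlated, after removal of group means, with r from -0.17 to 0.22, and the own number was the highest in 8 of 15 such pairs. Between 3p loss and 3q gain mRNA it was the highest in all 3 pairs, with r from 0.12 to 0.16, so a pairing of these libraries was not excluded, and 7 of 37 named calls of the direct contrast were lost with the block.

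Without a filter, which adds genes near the floor, the arm shifts were -0.68 for 3p loss mRNA, 0.42 for 3q gain, -0.92 for RPF and -0.70 for 8p loss. With a mean level of at least 10 they were -0.89, 0.56 and -0.95 in the mRNA sets, and with pseudocount 0.1 they were -0.98, 0.56 and -0.95. With prior count 0.5 the RPF shift was -1.08. A pseudocount of 1 pulls log2 changes of low-level genes toward 0 by construction. The mRNA shares of the copy-number change therefore depend on it. At a mean level of at least 10 those shares were 0.940 in 3p loss, 0.890 in 3q gain and 0.851 in 8p loss. The RPF share rests on edgeR changes without that pseudocount, so mRNA and RPF shares are not on the same scale. With pseudocount 0.1 the mRNA arm shifts lay closer to the copy-number changes of -1 for loss and 0.585 for gain than in the main setting. At least part of the departure from the copy number in mRNA therefore came from the pseudocount. The shares themselves were not computed with pseudocount 0.1. The difference between complex and other 3p genes in 3p loss mRNA, which did not pass, turned from -0.089 to 0.35 with ribosomal proteins left out. Of the 16 lists called in RPF, 3 were lost with replicates 1 and 2 summed, 3 with the altered arms kept in and 4 without several chromosomes with other shifted segments. With an estimated correlation, camera called 0 lists in 3p loss mRNA, 0 in 3q gain, 0 in their direct contrast, 0 in RPF, 0 in translational efficiency and 0 in 8p loss, with 3, 1, 1, 4, 3 and 8 at an unadjusted p under 0.05. At a mean level of at least 10, r was 0.49 between mRNA and RPF of 3p loss and -0.20 between RPF and 8p loss. Between 3p loss and 3q gain, r was 0.81 over genes past the threshold in either, a set chosen for large changes.

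With 1 library left out, counts ranged from 990.0 (without 3p loss replicate 1) to 1546 in 3p loss mRNA. They ranged from 110 (without 3q gain replicate 3) to 634 in 3q gain and from 187 (without 3q gain replicate 2) to 475 in their direct contrast. In 3q gain the other counts that fell by more than 1.5 times were 149 without 3q gain replicate 2, 273 without WT replicate 2 and 294 without WT replicate 3. In 3p loss mRNA such a count was 1062, without WT replicate 3, and in the direct contrast they were 191 without 3p loss replicate 1, 226 without 3q gain replicate 1 and 235 without 3q gain replicate 3. Fewer libraries lower the power of each test. Lists called in the direct contrast ranged from 5 to 12, and the RPF shift of 3p from -1.06 to -1.003. Footprints of VHL changed direction, from -0.31 without RPF 3p loss replicate 3 to 0.16 without RPF 3p loss replicate 1, and the cause was not tested.

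Of the called genes the rule names, a call was lost in at least 1 alternative for 34 of 89 genes in 3p loss mRNA, 47 of 61 in 3q gain and 17 of 37 in the direct contrast. The same held for 7 of 96 in RPF, 22 of 80 in translational efficiency and 5 of 103 in 8p loss. Summing RPF replicates 1 and 2 alone lost 7 of these in RPF and 22 in translational efficiency. Depth limits RPF calls among genes with few counts, and it is unknown for the mRNA sets.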

Other observations

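In 8p loss, replication genes were lower by a median of -0.57 over 42 genes (camera adjusted p = 1.25e-06, adjusted p = 0.314 with an estimated correlation), with 34 lower and 5 higher over all genes and adjusted over the list alone. The helicase gene MCM3 stood at -0.83 ± 0.03. Squamous differentiation markers were lower by -1.37 over 18 genes (camera adjusted p = 9.85e-05, adjusted p = 0.102 with an estimated correlation), with 14 lower and 2 higher over all genes and 15 and 2 adjusted over the list alone. Endoplasmic reticulum chaperones were higher by 0.29 over 24 genes (camera adjusted p = 0.000128, adjusted p = 0.142 with an estimated correlation), HSPA5 by 0.69 ± 0.03, with 21 higher and 2 lower over all genes and adjusted over the list alone. Inflammatory NF-kappa-B targets were higher by 0.42 over 31 genes (camera adjusted p = 0.0042, adjusted p = 0.142 with an estimated correlation). The cytokine gene IL1B (1.10 ± 0.03) was among 18 higher, with 6 lower, over all genes and 19 and 6 adjusted over the list alone.

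In RPF of 3p loss, squamous differentiation markers were higher by 2.62 over 13 genes (camera adjusted p = 0.00899, adjusted p = 0.242 with an estimated correlation), KRT10 by 3.18 ± 0.19, with 9 higher and 2 lower over all genes and adjusted over the list alone. Lysosome and autophagy genes were higher by 0.45 over 30 genes (camera adjusted p = 0.00299, adjusted p = 0.242 with an estimated correlation). The protease gene CTSD (1.72 ± 0.11) was among 16 higher, with 2 lower, over all genes and adjusted over the list alone.

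In RPF, 7q from 150 to 160 Mb had a median of -1.22, and it stood at -0.85 in 3p loss mRNA and -0.52 in 3q gain mRNA. The shift in 3q gain mRNA was not confined to that end. There, the windows from 70 to 90 Mb and from 110 to 160 Mb of 7q had medians of -0.87 to -0.50. On 7q as a whole, 3q gain replicate 1 departed from its group by 0.53. In 8p loss, 60 to 70 Mb of chromosome 20 had a median of 0.84 and 160 to 170 Mb of chromosome 6 of 0.78. Distal 22q had a median of 0.02 in 8p loss. Mitochondrial genes held 17.9 to 20.2% of the TPM sum in the chromosome 8 set. The segments and shares of this paragraph were looked at only after the results were seen.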
